A study of Homo sapiens with 6 samples.

How the data were processed

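Gene expression was measured in 6 samples of the human keratinocyte line HaCaT, 3 labelled shControl and 3 labelled shTP63, with RNA collected 72 hours after lentiviral knockdown. Groups and replicate numbers were taken from the sample titles. Per the labels' protocols, total RNA was isolated on columns and cDNA synthesis was primed with oligo-dT carrying a T7 promoter, followed by in vitro transcription into biotinylated cRNA, so each array was read in 1 colour. The annotation is of a whole-transcript type of array, which is not usually labelled this way, so the labelling used is uncertain, and with it what the values of RNAs without a poly(A) tail measure. Per the submitters' processing notes, the values were made with RMA (robust multi-array average) in R 2.15.1. RMA corrects the background, normalizes the arrays to a common distribution and summarises the probes of a probe set, so differences shared by all probe sets of an array are removed before deposit. The deposited values were intensities on a linear scale, with medians of 173 to 190 per array, and log2 was taken of them here, although the tests had been planned for log2 values. At each rank the sorted log2 values of the arrays lay within 0.0899 of the mean of all arrays. The sources used here give no further filter, and all columns of values were used.

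Each array held 32321 probe sets. Names came from the platform annotation supplied for this work, which gave 19158 probe sets 1 gene, 1388 several genes and left 11775 unlisted. Of the probe sets with 1 gene, 19128 matched a gene of the RefSeq annotation of GRCh38.p14 by its Entrez identifier, and each of these already carried the symbol given there. The build behind the array was not given in the sources used here, so no coordinates are printed and the annotation served only for names and for which genes lie within others. Probe sets with several genes or none entered no test of genes. For each of the 18404 genes tested, the probe set with the highest mean log2 value over the 6 arrays was used. Several probe sets existed for 637 genes, and in 20 of these probe sets passed in opposite directions. TP63 was not analysed here.

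The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, no covariate), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Differences are shTP63 minus shControl on the log2 scale. In these data 22 gene lists, holding 674 measured of 714 listed genes, were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists, and p-values were also adjusted over the list alone. The lists, the tests, the alternatives and the naming rule were fixed before the data were examined, and the lists came from general knowledge, not from these samples. The rule named the p63, Hippo-YAP and ACTL6A genes the series is about, the 10 largest rises and 10 largest falls among genes past the threshold whose groups did not overlap, and in each list the up to 3 members with the smallest adjusted p. It gave 87 genes. A further 50 genes and 15 gene families were chosen after the data were examined and are marked as such. The 95th percentile of the mean level of 360 olfactory receptor genes, 6.81 on the log2 scale, served as a measure of background, which limits the precision for dim probe sets: a true change there is compressed. Arrays give no counts, so precision rests on the 3 arrays per group, with a median within-group SD of 0.065.

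Alternatives were the replicate number as a block, another quantile normalization, centring on the array median, leaving out the dimmest 40% of probe sets, the mean of all probe sets of a gene, a trended robust prior, array weights, each array left out in turn, all probe sets tested, an unmoderated test, a threshold of 0.01, and for the lists an estimated correlation, fry and ranks. Cyclic loess and quantile normalization over the probe sets with 1 gene were added after seeing the data. The steps were tested on simulated data with the spread of this comparison over 18404 genes. In 10 simulations with 200 changed genes each, the fit recovered 13.8% of genes changed by 0.2 on the log2 scale, 85.4% of those changed by 0.5 and 98.5% of those changed by 1, with 3.87% false calls. In 20 simulations of the list test 0 of 440 tests of unchanged lists passed with limma's camera, and the planted list was found in 20. Those simulations drew genes independently of each other, unlike the real arrays. The simulations of genes held 200 changed genes each, whereas 7634 genes passed in the data. The adjusted threshold was therefore stricter in the simulations, and the recovered shares need not hold for this comparison.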

Results

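Messenger RNA was measured on 6 arrays of HaCaT cells, a spontaneously immortalised human keratinocyte line, 72 hours after lentiviral delivery of a short hairpin RNA. In 3 samples the hairpin was directed against TP63 (shTP63) and 3 samples received a control vector (shControl). TP63 encodes p63, a transcription factor that maintains the basal layer of stratified epithelia. The series was collected to ask how p63 and ACTL6A, a subunit of the SWI/SNF chromatin remodelling complexes, act on Hippo-YAP signalling in squamous cell carcinoma. Each array held 32321 probe sets. The median log2 intensity was 7.45 ± 0.016 (SD, n = 3) in shControl and 7.56 ± 0.012 (SD, n = 3) in shTP63. Across probe sets, which are not independent replicates, arrays of the same group correlated at r of 0.996 to 0.998 and arrays of different groups at 0.988 to 0.991. The leading principal component carried 80.7% of the variance of the log2 values. The number of arrays limits the precision, and the median standard error of a gene's log2 difference was 0.053. Nothing in the labels says that the replicates were separate cultures, so the p-values measure the spread between these samples, which may be technical. The level of TP63 itself was not analysed here, so the knockdown was not checked on these arrays and every direction given here rests on the sample labels.

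The comparison of shTP63 with shControl asked which genes change when p63 is depleted. At the probe set used for each gene SAA2, an acute-phase serum amyloid A gene, had the largest rise, from 8.38 ± 0.084 to 11.78 ± 0.032 (log2 intensity, SD, n = 3), a difference of 3.40 ± 0.053 (SE), or 10.5-fold. DSG4, a desmosomal cadherin of differentiating keratinocytes, fell from 10.53 ± 0.095 to 7.13 ± 0.058 and so fell by 3.40 on the log2 scale (SE 0.058), or 10.6-fold. In limma's moderated test 7634 of 18404 genes (41.5%) passed an adjusted p of 0.05, of which 3015 rose and 4619 fell. A change of at least 2-fold was seen in 125 genes, of which 82 rose and 43 fell. In 9454 genes (51.4%) the 3 values of one group all lay on one side of those of the other, which chance alone gives for 10% of genes. The split between rises and falls moved with the scaling. Falls made up 60.5% of the calls on the deposited scale, 69.0% after another quantile normalization and 81.7% (1782 rises, 7932 falls) with every array centred on its median, which moved the median difference of all genes from -0.01 to -0.12. They made up 49.7% (3704 rises, 3663 falls) after cyclic loess and 52.8% after quantile normalization over the probe sets with 1 gene, both chosen after seeing the data, and 47.6% (5884 rises, 5348 falls) over all probe sets. Centring and the other quantile normalization used all 32321 probe sets, and so also unlisted ones, which entered no test of genes. Unlisted probe sets had a median difference of 0.08, against -0.01 for listed ones.

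Other large rises were those of SAA1 (3.07 ± 0.116 SE), the matrix metalloproteinase MMP7 (2.95 ± 0.111), the protease inhibitor SERPINA3 (2.54 ± 0.095) and complement factor B, CFB (2.32 ± 0.087). The neutrophil chemokine CXCL8 rose by 2.30 ± 0.049, the BMP and activin pseudoreceptor BAMBI by 2.21 ± 0.041, the collagen cross-linking enzyme LOXL2 by 2.18 ± 0.050, the orphan receptor GPRC5B by 2.08 ± 0.059 and the calprotectin subunit S100A8 by 1.94 ± 0.081. SAA1 and SAA2 share near-identical sequence, so their separate values are uncertain. The other SAA2 probe set rose by 1.82, and the other CFB probe sets by 0.59 and 2.03. With its probe sets averaged SAA2 rose by 2.61, less than SAA1 and MMP7. Among the falls, the EGF family ligand EPGN fell by 1.79 (SE 0.079), with both groups under the 95th percentile of olfactory receptor genes (6.81), a class that served as a measure of background. SERPINA3 and S100A8 lay under it in shControl, so the sizes of their rises are uncertain. The receptor phosphatase PTPRZ1 fell by 1.58 (SE 0.063), to a level under the same percentile in shTP63, so the size of its fall is uncertain. The calpain subunit CAPNS2 fell by 1.58 (SE 0.041), PALMD by 1.55 (SE 0.066), carbonic anhydrase CA2 by 1.49 (SE 0.044) and the vacuolar proton pump subunit ATP6V1B1 by 1.46 (SE 0.052). The cytochrome P450 gene CYP2B6 fell by 1.41 (SE 0.079), the kallikrein KLK13 by 1.38 (SE 0.052) and the estrogen sulfotransferase SULT1E1 by 1.35 (SE 0.055). Adjusted p in limma ranged from 7.61e-09 for SAA2 to 3.75e-06 for CYP2B6 among these 20 genes. That the 3 shTP63 values all lay on one side of the 3 shControl values was a condition for naming these 20 genes. It also held for the other genes picked by the naming rule, as it did for 51.4% of all genes.

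**Figure D1:**
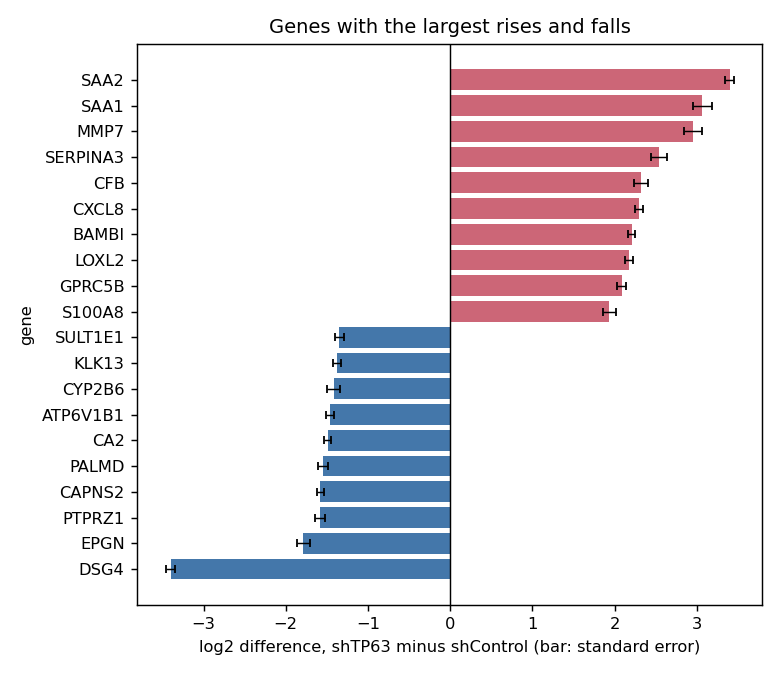
Horizontal bars give the log2 difference (shTP63 minus shControl, 3 arrays each) of the 10 genes with the largest rise and the 10 with the largest fall, and the error bars give the standard error. SAA2 (3.40) and DSG4 (-3.40) stand at the ends.

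Within the pathway that the series addressed, ACTL6A and both YAP-family coactivators were lower in shTP63, while WWC1 (KIBRA), an upstream activator of the Hippo kinases, was higher. ACTL6A (probe set 8084067) fell from 9.97 ± 0.049 to 9.60 ± 0.094 (SD, n = 3), so it fell by 0.36 on the log2 scale (SE 0.057, limma adjusted p = 0.000819). WWC1 (probe set 8109773) rose from 9.17 ± 0.028 to 9.72 ± 0.060, a difference of 0.54 (SE 0.047, limma adjusted p = 3.29e-05) or 1.46-fold. YAP1 fell by 0.27 (SE 0.047, limma adjusted p = 0.00158) and WWTR1, which encodes TAZ, fell by 0.20 (SE 0.043, limma adjusted p = 0.00535). The levels of ACTL6A, YAP1 and WWTR1 lay in the brightest of 5 equal bins of mean level or in the next. In each of those bins the median difference of all genes was -0.10. Over the alternatives ACTL6A ranged from -0.47 to -0.26 and YAP1 from -0.37 to -0.20, and both kept their calls. The WWTR1 call was lost after cyclic loess (difference -0.10, adjusted p = 0.115) and after quantile normalization over the probe sets with 1 gene (-0.11, adjusted p = 0.0765). Widely used YAP target genes were higher: ANKRD1 rose by 0.95 (SE 0.072), AXL by 0.85 (SE 0.050), CCN1 by 0.65 (SE 0.055) and CCN2 by 0.28 (SE 0.040), with limma adjusted p from 5.04e-06 to 0.000534. TP73, a relative of TP63, differed by -0.15 (SE 0.057) and did not pass (limma adjusted p = 0.0699), although it passed in 5 of 15 alternatives, among them the fit without shTP63 replicate 2 (adjusted p = 0.0324).

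Of 31 Hippo pathway components, 4 rose and 12 fell (4 and 16 adjusted over the list alone). WWC1, AMOT, FAT1 and TEAD2 rose, the last 3 of which were named after their values were seen, and TEAD2 lost its call after centring on the array median (difference 0.12, adjusted p = 0.0612). TAOK3, a kinase upstream of the Hippo kinases, fell by 0.44 (SE 0.047) and the LATS-binding LIM protein AJUBA by 0.32 (SE 0.041). The list did not pass limma's camera test (adjusted p = 0.130). Its median difference of -0.12 became -0.22 after centring, where 3 rose and 21 fell, and -0.02 after cyclic loess, where 6 rose and 11 fell. Its median level of 10.05 lay in the brightest of 5 equal bins of mean level. In that bin 932 of 3681 genes rose and 1618 fell, with a median difference of -0.10. Of 22 YAP/TAZ target genes, 11 rose and 4 fell, and the same counts came from p-values adjusted over the list alone. TGFB2, a TGF-beta ligand, rose by 0.89 (SE 0.040), whereas CCDC80 fell by 0.96 (SE 0.043), and the other falls, named after their values were seen, were those of RBMS3, FOXF2 and PTPN14. The list was higher as a set (camera adjusted p = 0.00763), a call lost at adjusted p = 0.283 with an estimated correlation. Its median difference was 0.11 on the deposited scale and -0.00 after centring on the array median, where 7 members rose and 7 fell. Of 29 SWI/SNF subunits, 1 rose (BRD9, named after its value was seen and lost without any 1 of 4 arrays) and 10 fell, both over all genes and adjusted over the list alone. BCL7B fell by 0.47 (SE 0.044), BCL7C by 0.45 (SE 0.051) and the ATPase SMARCA2 by 0.33 (SE 0.041), and the list did not pass (camera adjusted p = 0.0770). After centring 0 rose and 20 fell and the list passed as lower (adjusted p = 0.0356), whereas after cyclic loess 2 rose and 7 fell, and its median difference of -0.07 became -0.17 and -0.02. The median level of the SWI/SNF list, 9.69, lay in the next brightest bin. There 682 of 3681 genes rose and 1583 fell, with a median difference of -0.10.

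**Figure D2:**
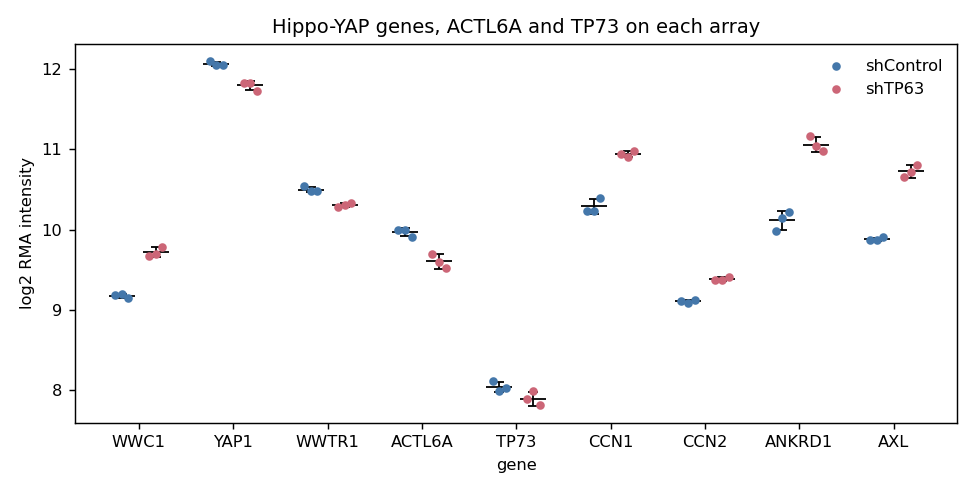
Points give the log2 intensity of 9 genes on each of the 6 arrays, shControl and shTP63 side by side, with black marks for the group mean and its SD (n = 3). WWC1, CCN1, CCN2, ANKRD1 and AXL lay higher on all shTP63 arrays, and YAP1, WWTR1, ACTL6A and TP73 lay lower, of which TP73 did not pass the test (adjusted p = 0.0699).

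Of 26 basal adhesion and hemidesmosome genes, 17 rose and 6 fell (19 and 6 adjusted over the list alone), and the list was higher as a set (camera adjusted p = 0.000176, but adjusted p = 0.245 with an estimated correlation). ITGB6 and ITGAV, the subunits of an integrin that activates latent TGF-beta, rose by 1.25 (SE 0.049) and 0.82 (SE 0.042), and the fibronectin receptor subunit ITGA5 rose by 1.42 (SE 0.067). Of the basal keratins named after their values were seen, KRT5 fell by 0.50 (SE 0.046) and KRT14 by 0.35 (SE 0.048). The differences in the list ranged from -0.91, for a member not named here, to 1.42. Of 37 genes reported elsewhere as p63 targets, 11 rose and 18 fell (12 and 19 adjusted over the list alone). GPX2, a glutathione peroxidase, fell by 0.92 (SE 0.046), while IGFBP3 rose by 0.83 (SE 0.054) and FRAS1, a basement membrane protein gene, by 0.69 (SE 0.046). This list holds genes described as activated and as repressed by p63 and did not pass (camera adjusted p = 0.552). After centring 8 rose and 20 fell, and after cyclic loess 14 rose and 17 fell.

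Of 56 keratinocyte differentiation genes, 19 rose and 15 fell, both over all genes and adjusted over the list alone, and the list did not pass (camera adjusted p = 0.138). LCN2, a bacterial siderophore-binding lipocalin, rose by 1.76 (SE 0.050) and S100A9, the partner of S100A8, by 1.16 (SE 0.049). Besides KLK13, the falls included IVL (involucrin), which fell by 1.04 (SE 0.044), KRT1, which fell by 1.02 (SE 0.073), and the cross-linking enzyme TGM1, which fell by 0.99 (SE 0.049). These 3 genes were named after their values were seen. The list's median difference was 0.04 on the deposited scale, -0.06 after centring on the array median (15 rose, 19 fell) and -0.00 after another quantile normalization.

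Of 23 simple epithelium keratin and junction genes, 13 rose and 4 fell, also adjusted over the list alone (camera adjusted p = 0.00484, adjusted p = 0.231 with an estimated correlation). After centring on the array median, 7 of them rose and 6 fell, and the median difference of 0.17 became 0.07. The tight junction protein cingulin, CGN, rose by 0.93 (SE 0.079), the membrane serine protease ST14 by 0.78 (SE 0.052) and the adhesion molecule EPCAM by 0.57 (SE 0.050), and the falls, named after their values were seen, were those of KRT19, RAB25, OVOL2 and TJP3, the last of which was lost in most alternatives. Of 32 mesenchymal and epithelial-mesenchymal transition genes, 17 rose and 3 fell, also adjusted over the list alone (camera adjusted p = 2.47e-05, adjusted p = 0.0585 with an estimated correlation). After centring, 12 rose and 8 fell, and the median of 0.18 became 0.07. TNC, a matrix glycoprotein, rose by 1.79 (SE 0.054) and N-cadherin, CDH2, by 1.59 (SE 0.047), 3.00-fold, and among genes named after their values were seen, fibronectin, FN1, rose by 1.51 (SE 0.050), while SNAI2, S100A4 and MYL9 fell, the last of which was lost in most alternatives. SNAI2 encodes a transcription factor of the same transition. Of 16 fibroblast markers, 5 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.0157, adjusted p = 0.384 with an estimated correlation). COL5A1 rose by 0.41 (SE 0.059), FAP by 0.37 (SE 0.062) and FBN1 by 0.35 (SE 0.064). The other changed markers, named after their values were seen, were COL1A1 and COL5A2, which rose, and DCN, which fell. COL1A1 was lost without shControl replicate 3 (adjusted p = 0.0603) and after centring. COL5A2, whose groups overlapped, and DCN were each lost without any 1 of 4 arrays, COL5A2 also under 2 scalings and DCN with the replicate number as a block (adjusted p = 0.0750). After centring, 3 members rose and 3 fell, with a median of 0.01. The list lost its call after another quantile normalization (adjusted p = 0.0823), 8 of its 16 members had mean levels under the 95th percentile of olfactory receptor genes, and FAP and FBN1 did so in both groups.

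Of 28 TGF-beta response genes, 14 rose and 8 fell, also adjusted over the list alone (camera adjusted p = 0.00753, adjusted p = 0.346 with an estimated correlation). Besides BAMBI, the activin subunit gene INHBA rose by 1.90 (SE 0.044), whereas ID2, an inhibitor of basic helix-loop-helix factors, fell by 1.11 (SE 0.043). The call was lost in the rank version of the test (adjusted p = 0.0558), and after centring 13 members rose and 9 fell, with a median of 0.01 against 0.12 on the deposited scale. Of 26 Notch pathway genes, 4 rose and 7 fell, also adjusted over the list alone (camera adjusted p = 0.974). The protease ADAM17 rose by 0.47 (SE 0.045), as did LFNG, NOTCH2 and ADAM10, named after their values were seen, and the Notch-responsive genes HES1 and NRARP fell by 0.41 (SE 0.046) and 0.36 (SE 0.042). After centring 4 rose and 13 fell, and after cyclic loess 7 rose and 7 fell.

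Interferon-stimulated and inflammatory genes formed the 2 lists with the smallest camera p-values at the preset correlation, and both were higher in shTP63. Of 38 interferon-stimulated genes, 24 rose and 7 fell (27 and 8 adjusted over the list alone), with a median difference of 0.33 (camera adjusted p = 1.84e-07, adjusted p = 0.0585 with an estimated correlation). IFI44 rose by 1.92 (SE 0.094) from a shControl level under the 95th percentile of olfactory receptor genes, so the size of its rise is uncertain. IFI6, a mitochondrial antiapoptotic protein gene, rose by 1.87 (SE 0.055) and the antiviral GTPase MX1 by 1.05 (SE 0.048). Of 34 cytokine, chemokine and NF-kappa-B genes, 24 rose and 3 fell, also adjusted over the list alone, with a median difference of 0.38 (camera adjusted p = 5.49e-10, adjusted p = 0.0585 with an estimated correlation). Besides CXCL8, the prostaglandin synthase PTGS2 rose by 1.90 (SE 0.041) and the NF-kappa-B feedback inhibitor TNFAIP3 by 1.67 (SE 0.044). The falls, named after their values were seen, were those of IL1RN (fell by 0.94, SE 0.041), IL18 and NFKB1, the last of which was lost without shControl replicate 2 (adjusted p = 0.0532), after cyclic loess (difference -0.09, adjusted p = 0.173) and after quantile normalization over the probe sets with 1 gene (-0.13, adjusted p = 0.0691). Of 17 immune and endothelial markers, 2 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.138). CD68 rose by 0.75 (SE 0.056) and CD14 by 0.70 (SE 0.064), both of which are best known from macrophages, and VWF fell by 0.18 (SE 0.048) with both groups under the 95th percentile of olfactory receptor genes, a call lost without shControl replicate 3 (adjusted p = 0.0558). The small nucleolar RNA genes on the same arrays had a median of 8.42 ± 0.067 in shTP63 against 8.03 ± 0.023 in shControl (log2, SD, n = 3).

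The cholesterol synthesis and NRF2 antioxidant lists were lower as sets at the preset correlation. Of 19 cholesterol synthesis genes, 1 rose and 11 fell (1 and 13 adjusted over the list alone, camera adjusted p = 0.000504, adjusted p = 0.289 with an estimated correlation). After centring 0 rose and 17 fell, and after cyclic loess 2 rose and 9 fell. The median of -0.22 became -0.32 and -0.16. Lanosterol synthase, LSS, fell by 0.91 (SE 0.051), the isomerase IDI1 by 0.88 (SE 0.055) and the thiolase ACAT2 by 0.62 (SE 0.045), and TM7SF2, named after its value was seen, rose but lost its call after centring (adjusted p = 0.0865). Of 26 NRF2 antioxidant genes, 2 rose and 17 fell (2 and 18 adjusted over the list alone, camera adjusted p = 0.000504, adjusted p = 0.231 with an estimated correlation). Besides GPX2, malic enzyme ME1 fell by 0.86 (SE 0.047) and the carbonyl reductase CBR1 by 0.67 (SE 0.041). The rises were those of the transporter genes ABCC1 and SLC3A2, named after their values were seen. The NRF2 list had a median difference of -0.32. Bright genes fell more often in general. The median level of the cholesterol list, 10.77, lay in the brightest of 5 equal bins, where 1618 of 3681 genes fell. That of the NRF2 list, 9.94, lay in the next bin, where 1583 of 3681 fell. The median difference of each bin was -0.10. Of 34 glycolysis and hypoxia genes, 8 rose and 14 fell (9 and 15 adjusted over the list alone, camera adjusted p = 0.472), with falls of the aldolase ALDOC by 1.33 (SE 0.051), the triose-phosphate isomerase TPI1 by 0.74 (SE 0.050) and NDRG1 by 0.63 (SE 0.046). After centring 5 members of this list rose and 20 fell, and after cyclic loess 10 rose and 10 fell. The other TPI1 probe set differed by 0.28 in the opposite direction. Mitochondrial ribosomal protein genes, a family chosen after the data were examined, had an array median of 9.87 ± 0.046 in shTP63 against 10.13 ± 0.025 in shControl on the same arrays (log2, SD, n = 3).

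Of 27 unfolded protein and integrated stress response genes, 15 rose and 8 fell, also adjusted over the list alone (camera adjusted p = 0.0157, adjusted p = 0.396 with an estimated correlation). The disulfide isomerase PDIA4 rose by 0.68 (SE 0.043), the co-chaperone DNAJB11 by 0.63 (SE 0.043) and calreticulin, CALR, by 0.58 (SE 0.041). Among members named after their values were seen, the chaperone HSPA5 rose by 0.56 (SE 0.045), and the transcription factors DDIT3 and ATF4 fell by 0.56 (SE 0.059) and 0.36 (SE 0.058), although ATF4 differed by 0.11 (adjusted p = 0.0639) when all its probe sets were averaged. The call of the list was lost in the rank version of the test (adjusted p = 0.0835) and without shControl replicate 1 (adjusted p = 0.0507), and after centring 13 members rose and 11 fell. Of 32 stress targets of the p53 family, 6 rose and 16 fell (7 and 16 adjusted over the list alone, camera adjusted p = 0.0802). After centring 4 rose and 19 fell, and after cyclic loess 10 rose and 16 fell. The median of -0.15 became -0.26 and -0.08. The death receptor TNFRSF10B rose by 0.90 (SE 0.045), while TP53INP1 fell by 0.73 (SE 0.049) and SFN, which encodes 14-3-3 sigma, by 0.60 (SE 0.042).

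Of 59 G2/M genes, 17 rose and 7 fell, also adjusted over the list alone (camera adjusted p = 0.0136, adjusted p = 0.554 with an estimated correlation). The cytokinesis protein anillin, ANLN, rose by 0.56 (SE 0.044), the nuclear envelope receptor LBR by 0.45 (SE 0.056) and CENPF by 0.34 (SE 0.044). This list had a median difference of 0.08. It turned to -0.03 after centring on the array median, where 8 members rose and 14 fell, and was 0.12 (23 rose, 7 fell) after another quantile normalization, 0.13 (29 and 6) after quantile normalization over the probe sets with 1 gene and 0.17 (33 and 4) after cyclic loess. Its call was lost without shControl replicate 1 (adjusted p = 0.0698). Of 52 G1/S genes, 13 rose and 8 fell (14 and 8 adjusted over the list alone, camera adjusted p = 0.130). With 1 array left out the falls numbered 3 to 7, and 4 with the replicate number as a block. The exonuclease EXO1 rose by 0.47 (SE 0.059), and the uracil glycosylase UNG and the replication protein RPA2 fell by 0.67 (SE 0.058) and 0.37 (SE 0.053). The G1/S list passed after another quantile normalization (adjusted p = 0.000624), cyclic loess (adjusted p = 0.00144) and quantile normalization over the probe sets with 1 gene (adjusted p = 0.00296), each time as higher, whereas after centring 7 members rose and 18 fell and its median of 0.02 became -0.09. Of 10 melanocyte markers, 1 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.653): KIT fell by 0.54 (SE 0.101), with both groups under the 95th percentile of olfactory receptor genes, and PMEL rose by 0.25 (SE 0.050). PMEL lost its call after another quantile normalization (difference 0.13, adjusted p = 0.0739) and after centring (0.14, adjusted p = 0.0528).

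In all, 12 of the 22 lists passed camera with its preset correlation of 0.01, 10 higher and 2 lower in shTP63. With a correlation estimated for each list, limma's camera passed 0 lists, with adjusted p from 0.0585 to 0.985, and 3 lists had an unadjusted p under 0.05. Limma's fry, which tests a list against no change rather than against other genes, passed 16 lists.

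**Figure D3:**
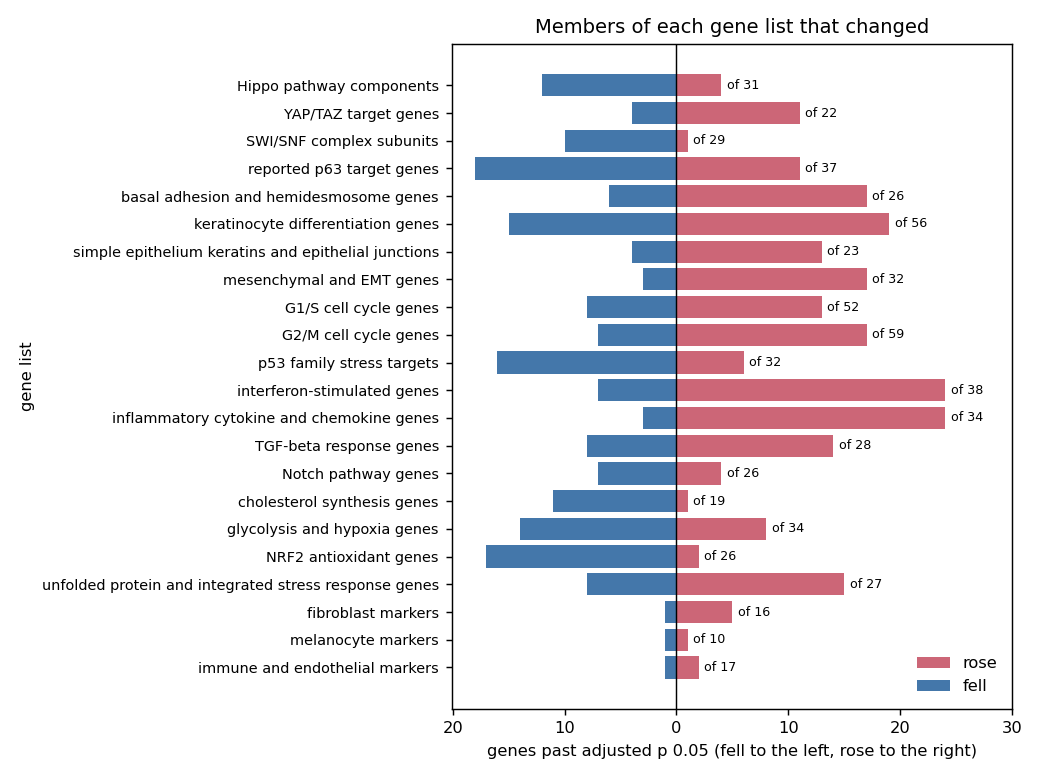
Bars to the right give the number of members that rose and bars to the left the number that fell (limma adjusted p under 0.05) for each of the 22 lists, with the number of measured members at the right. The inflammatory list had 24 rises and 3 falls of 34, and the NRF2 list 2 rises and 17 falls of 26.

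Classes of probe sets outside these lists also differed between the groups. Their tests were chosen after the data were examined. Of 176 small nucleolar RNA genes, 123 rose and 2 fell (SNORD114-2 and SNORD115-38, named after their values were seen), with a median difference of 0.32 (camera adjusted p = 9.47e-19, adjusted p = 0.187 with an estimated correlation). Of 61 cytosolic ribosomal protein genes, 51 fell, with a median difference of -0.33 (camera adjusted p = 4.81e-14, adjusted p = 0.187 with an estimated correlation). Of 73 mitochondrial ribosomal protein genes, 57 fell, with a median of -0.28 (camera adjusted p = 3.49e-12, adjusted p = 0.187 with an estimated correlation). The 360 olfactory receptor genes had a median difference of 0.01. That median was -0.07 after another quantile normalization, -0.10 after centring and -0.00 after quantile normalization over the probe sets with 1 gene, while the other 3 families kept their direction under the 4 other scalings. The 4091 probe sets that the annotation does not list and whose numbers lie below every listed number had an array median of 8.22 ± 0.062 in shTP63 against 7.66 ± 0.027 in shControl (log2, SD, n = 3).

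**Figure D4:**
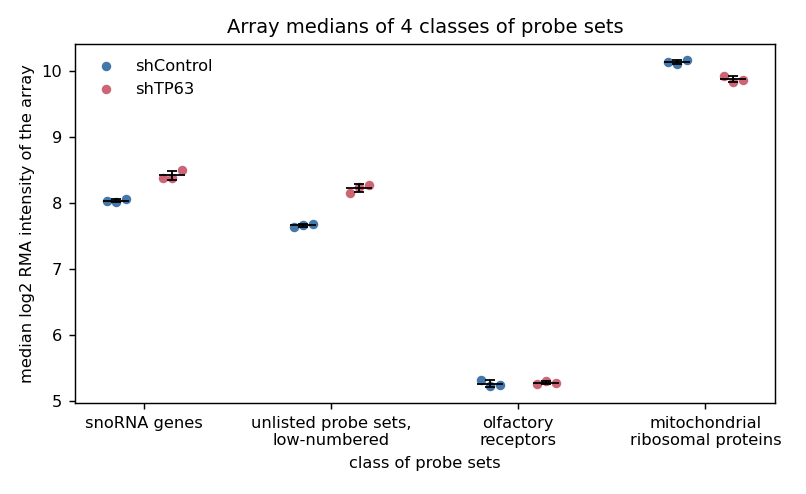
Points give the median log2 intensity of 4 classes of probe sets on each of the 6 arrays, and black marks give the group mean with its SD (n = 3). The small nucleolar RNA genes lay at 8.42 ± 0.067 in shTP63 against 8.03 ± 0.023 in shControl, and the mitochondrial ribosomal protein genes at 9.87 ± 0.046 against 10.13 ± 0.025.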

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

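The tests on cyclic loess and on lists matched to the small nucleolar RNA genes and to the interferon-stimulated and inflammatory genes were chosen only after the results were seen, as were the gene families and classes of probe sets in this part.

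Probe sets that the annotation does not list entered no test of genes or lists, and more of them rose than fell in shTP63. In limma 2939 of 11775 rose and 844 fell, and 276 were at least 2-fold higher against 1 that was at least 2-fold lower. Of the 4091 with numbers below every listed number, 1785 rose and 409 fell. Their median difference was 0.35, with 0.55 at mean log2 levels of 5 to 9 and -0.07 above 11. The sources used here do not say what these probe sets measure.

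The small nucleolar RNA genes rose by a median of 0.32 (bootstrap interval 0.26 to 0.36 over 176 genes). The intervals and random lists in this part resample genes, which are not independent replicates. They do not measure the spread between arrays. A lift shared by tested genes of the same level is argued against as the whole cause by 10000 random lists matched on level. Their middle 95% ended at 0.0130, and they were drawn from tested genes alone. Unlisted low-numbered probe sets at levels of 5 to 9, which did not enter these lists, had a median of 0.55. Of 24 bitter taste receptor genes 10 rose. Genomic DNA, or another lift shared with such probe sets, therefore stays open. A higher level of the genes that host the small nucleolar RNA genes is argued against as the whole cause for the 85 that lie inside a tested gene. Their 65 host genes had a median of -0.118 (interval -0.22 to -0.07), and 4 of these rose and 30 fell. A host was taken as the smallest tested gene around the small nucleolar RNA gene, on either strand. The other 91 lie inside no tested gene, so the level of their hosts is unknown. More unspliced or intron RNA in the shTP63 samples stays open. The median of the 85 inside a tested gene exceeded that of the 91 outside one by 0.0294 (interval -0.04 to 0.21). That split cannot decide the question, because 89 of those 91 lie inside a gene that was not tested. A response to p63 depletion stays open as well and was not tested apart from these.

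The cytosolic and mitochondrial ribosomal protein genes fell by medians of 0.33 and 0.28. A scaling that moved bright genes down is argued against as the whole cause, because after cyclic loess the mitochondrial median was -0.192, outside the -0.07 to 0.07 of 10000 random lists matched on level, and the cytosolic median was -0.28, outside -0.06 to 0.11. Short gene span is argued against as the whole cause by lists matched on level and span, whose lower bound was -0.161 for the mitochondrial and -0.18 for the cytosolic family. The families were chosen after the data were examined, so the lists show only that other genes of the same level and span fell less. Span was the genomic length of a gene, so the length of its transcript was not matched. A difference in RNA quality and a response to p63 depletion stay open and were not tested.

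The interferon-stimulated and inflammatory lists were higher by medians of 0.33 and 0.38. A lift shared by genes of like level and gene span is argued against as the whole cause by 10000 random lists matched on both. Their middle 95% ended at 0.0357 for the interferon-stimulated and 0.0546 for the inflammatory list. Both lists had already passed against other genes, so the random lists show only that genes matched on level and span rose less. More intron RNA stays open, from these genes or in general, since whether it follows level and gene span on these arrays was not tested. A response to the TP63 hairpin other than through loss of p63 cannot be told apart from the loss itself, because the series holds 1 TP63 hairpin group. A response to p63 depletion stays among the open explanations.

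The 6 arrays can be split into 3 and 3 in 10 ways, which is too few for a share under 0.05. For the genes changed, the genes changed at least 2-fold and the lists passed, 1 of the 10 splits, the real one, gave a result as large. It gave 7634 genes, 125 at 2-fold and 12 lists, and the highest values of the other 9 splits were 0 genes, 0 at 2-fold and 8 lists in limma, with at most 522 genes at an unadjusted p under 0.05. Each of those 9 splits mixes shControl and shTP63 arrays on both sides, so the difference between the groups adds to the spread within each side. Their low counts of genes therefore do not show what chance gives, and no conclusion is drawn from them. Lists thus passed in splits where limma called 0 genes. Those splits keep part of the difference between the groups. The correlation estimated on the real groups was also above the preset 0.01 for most of the 12 lists, so p-values at the preset value may be too small. How much each of these contributed was not tested.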

How the results depend on the processing

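Cyclic loess and quantile normalization over the probe sets with 1 gene were chosen after seeing the data, as were the gene families. The count of changed genes ranged from 5564 at a threshold of 0.01 to 11232 over all probe sets, and from 6483 (without shControl replicate 3) to 7290 with 1 array left out. The replicate numbers did not pair the samples (correlations of deviations -0.150, -0.037 and 0.125, and only replicate 3 correlated best with its own number). With the replicate number as a block 7165 genes changed, of which 6995 were shared in direction with the unblocked fit, and the block changed no call of a list or of a gene named by the rule. Centring on the array median gave 1782 rises and 7932 falls, because it moved the median difference of all genes to -0.12. That array median was taken over all 32321 probe sets, unlisted ones included. Testing all probe sets gave 5884 rises and 414 changes of at least 2-fold, since unlisted probe sets then entered. The number at 2-fold was otherwise 111 to 146. Of the 87 genes named by the rule 83 kept their direction and side of the threshold throughout. TP73 passed without shTP63 replicate 2 (adjusted p = 0.0324, range over its alternatives 0.00306 to 0.201) and VWF failed without shControl replicate 3 (adjusted p = 0.0558). WWTR1 and PMEL failed under the scalings given in the report. Of the 50 genes named after their values were seen, 30 kept both throughout and 1 reversed (ATF4, 0.11 with its probe sets averaged). With 1 array left out, NFKB1 was lost without shControl replicate 2 (adjusted p = 0.0532) and COL1A1 without shControl replicate 3 (0.0603). BRD9, TJP3, MYL9, DCN, COL5A2, SNORD114-2, SNORD115-38, NDUFB9, H1-9P, MIR129-2, OR5M11, OR6K2 and OR6M1 were lost in at least 2 such fits each, with adjusted p up to 0.140 (MYL9 without shControl replicate 1). The block ended the calls of TJP3, MYL9, DCN, SNORD115-38, NDUFB9, MIR129-2, OR5M11 and OR6M1.

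With an estimated correlation the 12 passed lists failed, at adjusted p of 0.0585 for the mesenchymal, interferon-stimulated and inflammatory lists, 0.231 for the epithelial junction and NRF2 lists, 0.245 for basal adhesion, 0.283 for YAP/TAZ targets, 0.289 for cholesterol synthesis, 0.346 for TGF-beta, 0.384 for fibroblast markers, 0.396 for the unfolded protein response and 0.554 for G2/M. That version of the test uses the 4 residual degrees of freedom of the 6 arrays, and the estimated correlation was above the preset value for 11 of these lists and -0.017 for the mesenchymal list. By fry, which asks another question, Hippo components (0.000726), SWI/SNF (0.000170), p63 targets (0.00184), p53 family targets (0.000396) and glycolysis (0.00122) passed as lower, and G2/M did not pass (0.0530). SWI/SNF (0.0356) and differentiation genes (0.0337) passed after centring, immune and endothelial markers without the dimmest probe sets (0.0400), and G1/S after another quantile normalization (0.000624), cyclic loess (0.00144) and quantile normalization over the probe sets with 1 gene (0.00296). Fibroblast markers failed after another quantile normalization (0.0823), and TGF-beta (0.0558) and the unfolded protein response (0.0835) by ranks. With 1 array left out adjusted p was 0.00420 to 0.0698 for G2/M, 0.00844 to 0.0507 for the unfolded protein response and 0.802 to 0.986 for Notch, and the highest values of the former 2 came without shControl replicate 1. The direction reversed, with no call on either side, after another quantile normalization for p63 targets (0.577), glycolysis (0.983), melanocyte markers (0.983) and Notch (0.804), and for Notch also without the dimmest probe sets (0.722), with probe sets averaged (0.923), a trended prior (0.937), array weights (0.993), without shControl replicate 1 (0.908), without shTP63 replicate 1 (0.840), cyclic loess (0.852) and quantile normalization over the probe sets with 1 gene (0.857). For the other changes of lists the cause was not tested. The median differences of G1/S (-0.09) and of immune and endothelial markers (-0.06) also turned negative after centring. No alternative of the TP63 level was run, because that gene was not analysed here. Signal over background limits the dim lists: 12 of 17 immune and endothelial, 6 of 10 melanocyte and 8 of 16 fibroblast markers lay under the 95th percentile of olfactory receptor genes.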

Other observations

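All gene families in this part were chosen after the data were examined. Genes of respiratory complex I fell in shTP63: of 33 NDUF genes 23 fell and 1 rose (NDUFB9, lost without any 1 of 4 arrays, with the replicate number as a block and after centring), with a median difference of -0.22 (camera adjusted p = 1.69e-05, adjusted p = 0.187 with an estimated correlation). Of 62 histone genes 33 fell and 5 rose (H1-1, H1-9P, H2AC14, H3C3 and H4C7), with a median of -0.19 (camera adjusted p = 0.000419, adjusted p = 0.20 with an estimated correlation). H1-9P and H4C7 were lost after another quantile normalization and after centring, and near-identical sequence among histone genes makes single members uncertain. Of 11 metallothionein genes, which bind zinc and copper, 8 fell, with a median of -0.18 (camera adjusted p = 0.00301, adjusted p = 0.221 with an estimated correlation). Of 36 proteasome subunit genes 17 fell, with a median of -0.12 (camera adjusted p = 0.000692, adjusted p = 0.206 with an estimated correlation), a call also lost after another quantile normalization (adjusted p = 0.0775). These 4 medians stayed below 0 under the 4 other scalings but changed in size. After centring and after cyclic loess they were -0.32 (30 fell) and -0.12 (15 fell, 3 rose) for NDUF genes, -0.30 (43 fell, 3 rose) and -0.12 (29 fell, 8 rose) for histone genes, -0.29 (10 fell) and -0.16 (6 fell) for metallothionein genes and -0.23 (32 fell) and -0.06 (9 fell, 2 rose) for proteasome genes. Genes of the ZNF family had 126 falls and 43 rises among 480, and the family did not pass (camera adjusted p = 0.185), although it passed as lower after another quantile normalization (adjusted p = 0.0346) and by fry (adjusted p = 0.00196). After centring on the array median 237 fell and 18 rose.

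Of 11 HLA genes 6 rose, with a median of 0.21 (camera adjusted p = 0.00263, adjusted p = 0.187 with an estimated correlation). The HLA median was 0.10 after another quantile normalization (4 rose) and 0.10 after centring (4 rose, 1 fell). Of 24 bitter taste receptor genes 10 rose, with a median of 0.15 (camera adjusted p = 0.00162, adjusted p = 0.187 with an estimated correlation), and all 24 had mean levels under the 95th percentile of olfactory receptor genes. Their median was 0.07 (7 rose) and 0.04 (7 rose, 2 fell) in the same 2 scalings. Of 43 collagen genes 13 rose, with a median of 0.08 (camera adjusted p = 1.69e-05, adjusted p = 0.214 with an estimated correlation) that was -0.02 after another quantile normalization and -0.03 after centring. Of 329 solute carrier genes 113 rose and 33 fell, with a median of 0.07 (camera adjusted p = 1.67e-06, adjusted p = 0.187 with an estimated correlation) that was -0.01 (105 rose, 51 fell) and -0.03 (75 rose, 69 fell) in the same 2 scalings. Of 173 microRNA genes 52 rose and 2 fell (MIR124-3 and MIR129-2), with a median of 0.08 (camera adjusted p = 4.16e-06, adjusted p = 0.187 with an estimated correlation) that was -0.02 after centring, where 29 rose and 24 fell (30 and 12 after another quantile normalization), and of 23 spliceosomal and other small structured RNA genes 10 rose, with a median of 0.18 (camera adjusted p = 0.000320, adjusted p = 0.20 with an estimated correlation) that was 0.11 after another quantile normalization and 0.07 after centring (7 rose in each) and 0.13 without shControl replicate 1 (5 rose). Mean levels of 119 of the 173 microRNA genes, MIR124-3 and MIR129-2 among them, lay under the 95th percentile of olfactory receptor genes. The call of MIR129-2 was lost with some arrays left out. Of 360 olfactory receptor genes 20 rose and 5 fell (OR10H4, OR2B6, OR5M11, OR6K2 and OR6M1), and the family did not pass (camera adjusted p = 0.0768, 0.0276 without shControl replicate 1, 0.0368 without shTP63 replicate 1, 0.0416 by ranks and 0.0474 with array weights). The calls of OR5M11, OR6K2 and OR6M1 were lost with some arrays left out. The balance reversed with the scaling: 5 rose and 44 fell after another quantile normalization, and 2 rose and 75 fell after centring.

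Calls depended on signal level. In the dimmest of 5 equal bins of mean level 234 genes rose and 163 fell of 3681, and in the brightest 932 rose and 1618 fell of 3681. The brightest bin had a median difference of -0.10, against -0.12 for the proteasome subunit genes, whose median level of 11.03 lay in it.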
